A study of Mus musculus with 22 samples.

How the data were processed

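Droplet single-cell RNA sequencing (10x Genomics) had been done on mouse embryonic stem cells, on chemically induced totipotent stem cells in 2 forms whose labels read TAW and TAWa, on embryo models labelled ciToti with a number, and on natural mouse embryos. The 22 libraries fell into 19 groups. The ciToti8 group had 3 numbered libraries, ciToti10 had 2, and each other group had 1. What TAW, TAWa and the ciToti numbers stand for is not given in the sources used here. Per the labels' protocols, stem cells were taken from the culture plate, E3.5 and E4.5 embryos and ciToti1 to ciToti4 models were picked by hand, E6.5 to E8.5 embryos and ciToti7 to ciToti10 models were dissociated whole with their extraembryonic parts, and cardiac tissue was dissected from E10.5 embryos and ciToti12 models. The labels did not say whether the numbered libraries came from separate cultures, so p-values measured only the spread between these libraries, which may be technical.

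The values analysed were raw counts of unique molecular identifiers (UMIs) per gene and cell barcode, as the authors deposited them, with no normalisation. Reads had been aligned and counted with Cell Ranger 7.1.0 against mm10, per the submitters' processing notes. Per the file headers, the counts came from Cell Ranger 9.0.0 for 3 libraries (mESC, ciTotiSC TAW and ciTotiSC TAWa), 7.2.0 for 2 libraries (ciToti1 and ciToti2) and 7.1.0 for the other 17. The notes and the headers thus named different versions for 5 libraries. The files held 213395 barcodes and 32285 genes, of which 32158 were found by identifier in the GRCm38 (mm10) annotation and 127 were not, and 40 symbols occurred more than once. Coordinates are those of that annotation. Genes with near-identical copies, such as Gm10260, Tpm3-rs7, Hba-a1 and Hba-a2, the Zscan4 family, Usp17l and Tdpoz genes, can share reads, and their levels are uncertain.

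Barcodes with at least 500 genes, at least 1000 UMIs and at most 20% mitochondrial UMIs were kept, which left 183921 cells, between 59.8% and 97.8% of a library's barcodes. Total UMIs per library ranged from 16052913 to 152556715 and the median per kept cell from 1680 (ciToti1) to 24882 (ciToti8 replicate 3). No correction for free RNA was made. Doublets were scored with Scrublet, whose own threshold marked under 0.5% of cells in 8 libraries (range 0.0% to 15.9%) and was not used. Doublets were therefore kept, and an alternative left out the highest-scoring cells up to the share expected at 0.8% per 1000 cells (0.54% to 14.5%, capped at 15%). The numbered libraries of a group were not copies of each other, since the chi-square per degree of freedom of their counts lay between 284.9 and 480.2.

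Cells were clustered jointly within 3 sets of libraries. These sets were the stem cells with ciToti1 to ciToti4, E3.5 and E4.5, then ciToti7 to ciToti10 with E6.5 to E8.5, and the 2 heart libraries. Counts were scaled to 10000 UMIs per cell and log-transformed, and 2000 variable genes, 40 principal components, 15 neighbours and Leiden resolution 1.0 were used (scanpy 1.11.5, igraph 0.11.9). A cluster was named after a cell type when at least 3 and at least 50% of that type's detected markers, from 34 lists, stood at least 2-fold above the mean of the other clusters with at least 10 CPM (UMI counts scaled by the library's total, pseudocount 5 CPM). Clusters failing this rule, or with a median depth that was below that of their own library even when multiplied by 3, and no marker of that type among the top 10 genes (at least 20 CPM), stayed unnamed. So did clusters with more markers of another type than of their own among these top 10 genes. The marker lists were fixed in advance and the thresholds were set after the data had been seen, so the shares of unnamed clusters are given where they are large. Named classes are called "like" throughout. Shares of cells carry exact Clopper-Pearson 95% intervals, and a share of 0 carries the limit of 3 counts.

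Counts were summed over the kept cells of each library. Such sums mix the cell classes present with expression within them. For ciToti8, ciToti10, E7.5 in utero and E8.5 in utero, a single model of 7 libraries was fitted with the quasi-likelihood test of edgeR 4.0.16 (TMM scaling, filterByExpr, Benjamini-Hochberg adjustment at 0.05), with 3 residual degrees of freedom and a biological coefficient of variation of 0.495. TMM factors lay between 0.835 and 1.158. The single natural library of each stage was assumed to vary like the model libraries. The same contrasts were tested within each class that had at least 50 cells in every library compared, in fits with 3 residual degrees of freedom for endoderm-like and visceral endoderm-like cells, 2 for gut endoderm-like cells and 1 for erythroid-like, endothelial-like, extraembryonic mesoderm-like and cardiomyocyte-like cells. Gene lists (30 lists, 379 genes, of which 2 were not found under their symbols) were tested with limma 3.58.1's camera at a preset correlation of 0.01 and again with an estimated correlation, with Benjamini-Hochberg adjustment over the lists.

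All other comparisons set 1 library against 1 library. They have no test and no replicate check: levels are CPM of summed counts with exact Poisson 95% intervals, folds carry exact intervals from the 2 counts, and a fold against 0 UMIs is a lower bound against a floor of 3 counts. These intervals and floors cover counting error only. For a gene list, the median log2 fold of its members (pseudocount 1 CPM, members with a mean of at least 1 CPM, at least 3 members) is given with its percentile among 10000 random lists matched on mean expression within 100 neighbouring genes, and with their 95% range. Similarity to natural libraries was the Spearman correlation across the 2000 genes most variable among natural libraries, on log2(CPM + 1), where genes are not independent replicates. Cells using the 2-cell programme were counted after thinning every cell to 2000 UMIs, as those with at least 3 UMIs over 29 listed genes.

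Genes were named by a fixed rule. In tested contrasts these were up to 10 higher and 10 lower genes with an adjusted p under 0.05, at least 20 CPM in the higher group's mean and every library separated, by size of log2 fold. In single-library comparisons these were up to 10 genes each way with at least 50 CPM in the higher library, ranked by the interval bound nearest to no change. Numbered Gm gene models, Rik clones, mitochondrial and ribosomal protein genes were left out of the rule, and members of the described lists were added. Where another gene is named, it was chosen after its values were seen, and some genes that met the rule are not reported here. The groups, tests, lists, naming rule and most alternatives were chosen before the data were examined. Alternatives changed the scaling, the gene filter, the cell filter, the treatment of doublets, the test (DESeq2 1.42.0), the libraries in the fit and the clustering resolution. The tests were first run on simulated counts with known changes. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0, matplotlib 3.10.9 and R 4.3.3.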

Results

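The series set embryo models, which its title describes as made from chemically induced totipotent stem cells (ciTotiSC), beside the stem cells themselves and beside natural mouse embryos. RNA was measured in 22 single-cell libraries with 183921 cells after filtering. Stem cells gave 12416 cells from mouse embryonic stem cells (mESC), 8471 from ciTotiSC TAW and 10351 from ciTotiSC TAWa. Early models gave 18123 cells for ciToti1, 6609 for ciToti2, 10696 for ciToti3 and 5950 for ciToti4, and early embryos gave 2467 at E3.5 in utero and 4186 at E4.5 ex utero. Later models gave 10476 cells for ciToti7, 7428, 7036 and 3599 for the 3 ciToti8 libraries and 11568 and 5372 for the 2 ciToti10 libraries. Later embryos gave 5842 cells at E6.5, 9759 at E7.5 and 10042 at E8.5 in utero, with 10930 at E6.5 and 681 at E7.5 ex utero. Heart tissue gave 6625 cells for ciToti12 and 15294 for E10.5 embryos. Total counts ranged from 16052913 UMIs (E7.5 ex utero) to 152556715 UMIs (ciToti7).

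The stem cell libraries were compared for the genes that mark totipotency, each time 1 library against another, so that these comparisons and all others without a p-value have no replicate check and intervals that cover counting error only. In ciTotiSC TAW the 2-cell programme, a set of genes used by the embryo when its own genome is switched on, stood far above mESC, while naive pluripotency genes stood below. Zscan4d (ENSMUSG00000090714, chromosome 7, 11161374 to 11166159), a telomere regulator of the 2-cell embryo, read 803 CPM against 3.78, a fold of 213 (95% interval 195 to 233). Tcstv3 (ENSMUSG00000095821, chromosome 13, 120316878 to 120318178) was 390-fold higher (337 to 454) and Zfp352 (ENSMUSG00000070902, chromosome 4, 90218820 to 90225702), a retrotransposed zinc finger gene of the 2-cell stage, 835-fold higher (521 to 1434). Duxf3, the transcription factor Dux that opens this programme, read 36.9 CPM against 0.208, a fold of 178 (122 to 270). The median log2 fold of the list was 6.36, at the 100th percentile of random lists, whose 95% range was -0.30 to 0.26. Members of the Zscan4 family share sequence, so their separate levels are uncertain. The chemokine Ccl3 (129 CPM, 4195-fold, 1638 to 15398), Ankrd22 (213 CPM, 1970-fold, 1174 to 3605) and the lipid phosphatase Inpp4b (532 CPM, 1031-fold, 811 to 1330) were among the largest differences, and Ear1, an RNase of eosinophils, was at least 2618-fold higher.

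Genes of other programmes differed between ciTotiSC TAW and mESC as well. Naive pluripotency genes had a median of -1.64 (percentile 0.0, random range -0.42 to 0.31): the growth factor Fgf4 was 19.5-fold lower (18.3 to 20.7), the nuclear receptor Esrrb 5.73-fold lower (5.42 to 6.07) and Nanog 3.47-fold lower (3.36 to 3.6). Primitive endoderm genes had a median of 3.97 (percentile 100, range -0.45 to 0.39), with the endocytic adaptor Dab2 187-fold (148 to 239), the basement membrane collagen Col4a1 43.8-fold (41.0 to 47.0) and the transcription factor Gata6 21.8-fold higher (19.5 to 24.6). Retinoic acid response genes had a median of 2.96 (percentile 100, range -0.38 to 0.47). Cyp26a1, the enzyme that degrades retinoic acid, was 351-fold higher (299 to 416) and the receptor Rarb 44.7-fold higher (38.2 to 52.5). Hoxb1, with 2 UMIs in mESC, was 2875-fold higher (795 to 23751). Cholesterol synthesis genes had a median of 0.91 (percentile 99.99), with the demethylase Cyp51 3.01-fold higher (2.92 to 3.10). The metallothionein Mt2 (10.51-fold, 10.3 to 10.7) and Ldhb, a subunit of lactate dehydrogenase (14.1-fold, 13.3 to 14.8), were lower.

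In ciTotiSC TAWa the same lists lay on the same sides of mESC. The 2-cell programme had a median of 5.46 (percentile 100, random range -0.31 to 0.38), primitive endoderm genes 4.39 and retinoic acid response genes 2.95, while naive genes had -2.11 (percentile 0.0, range -0.47 to 0.37). Fgf4 was 63.8-fold lower (58.1 to 70.3), Nanog 11.1-fold lower (10.52 to 11.6), Cyp26a1 475-fold higher (404 to 562) and Zscan4d 106-fold higher (97.1 to 116). Set against TAW, TAWa had lower 2-cell genes (median -0.75, percentile 0.0, range -0.17 to 0.10) and higher primitive endoderm genes (median 0.86, percentile 100, range -0.22 to 0.16). Zscan4d was 2.0-fold lower (1.98 to 2.03), Zfp352 2.32-fold lower and Hoxb2, a hindbrain segment gene, 3.21-fold lower (3.12 to 3.30) in TAWa. The basement membrane genes Col4a2 (2.19-fold, 2.14 to 2.23) and Lamb1 (2.18-fold, 2.14 to 2.22) were higher. The largest folds belonged to the olfactory receptor genes Olfr1388 (285-fold, 208 to 403) and Olfr889 (49.0-fold, 44.2 to 54.5), and to Klhl24, a ubiquitin ligase adaptor (18.2-fold, 17.1 to 19.3; log2 fold 4.08, or 4.92 averaged over cells).

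Cells with at least 3 UMIs of the 2-cell programme, after thinning, made up 57.2% of TAW (exact 95% interval 56.1 to 58.3) and 52.2% of TAWa (51.2 to 53.2), against 0.199% of mESC (0.127 to 0.295). Without thinning the shares were 70.0%, 68.2% and 0.338%, and 678, 678 and 334 shallower cells were left out of the thinned ones. In extraembryonic endoderm-like cells, which should lack these genes, the share was 1.40% in TAW and 1.03% in TAWa, at median depths of 12131 and 13197 UMIs against 8471 and 9575 in 2C-like cells. The 2C-like class held 61.3% of TAW cells (60.2 to 62.3), mostly in cluster 3, and 55.9% of TAWa cells (54.9 to 56.8), mostly in cluster 11, against 0.217% of mESC. Naive pluripotent-like cells made up 96.9% of mESC and 1.98% of TAW. Extraembryonic endoderm-like cells, nearly all parietal, made up 17.8% of TAW and 27.2% of TAWa. Unnamed clusters held 18.8% and 16.8%, of which cluster 4 held 16.4% and 14.96%.

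**Figure D1:**
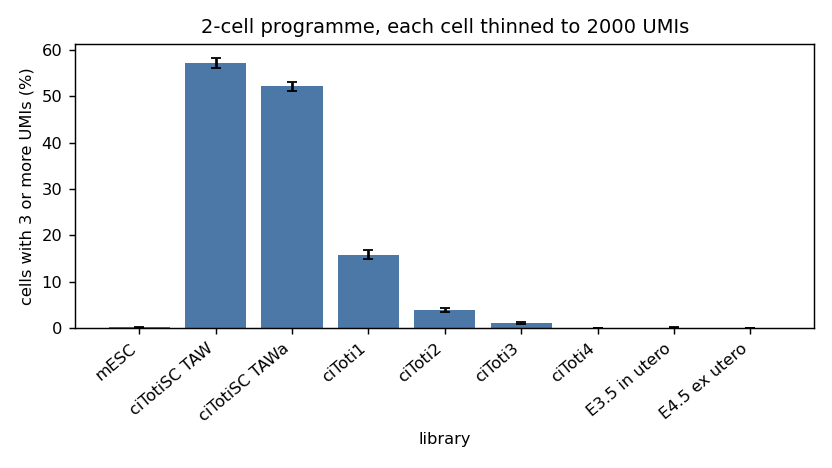
Share of cells (%) with at least 3 UMIs of the 2-cell programme after thinning to 2000 UMIs, with exact 95% intervals, in the stem cell, early model and early embryo libraries. The bars of ciTotiSC TAW (57.2%) and TAWa (52.2%) are the highest, ciToti1 to ciToti4 range from 15.9% to 0.019%, and E3.5 and E4.5 are at 0.

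The early models were compared in the order of their numbers. From ciToti1 to ciToti2, genes of the primitive endoderm, the layer that lines the blastocyst cavity and later forms the yolk sac, stood higher and 2-cell and naive genes lower. The primitive endoderm list had a median of 3.22 (percentile 100, random range -0.20 to 0.22): Ttr, a thyroid hormone carrier, was 103-fold higher (78.6 to 139), the endocytic receptor Cubn 35.0-fold (32.6 to 37.7) and Dab2 25.5-fold higher (24.2 to 26.9). The 2-cell list had a median of -1.34 (percentile 0.0, range -0.19 to 0.17), or -0.69 averaged over cells, with Tcstv3 4.15-fold (3.91 to 4.41) and Zscan4d 2.53-fold lower (2.46 to 2.60), and the naive list -0.85 (percentile 0.0), with Nr0b1 4.33-fold lower (4.15 to 4.52) and Nanog 3.0-fold lower (2.88 to 3.14). Median depth was 1680 UMIs per cell in ciToti1 and 17421 in ciToti2, and Lars2 (1146 against 218 CPM) and Cmss1 (1108 against 209 CPM) were also higher in ciToti1. The log2 fold of Lars2 was -2.39, or -1.39 averaged over cells.

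From ciToti2 to ciToti3, Hox groups 1 to 4, Wnt response and glycolysis genes stood higher and primitive endoderm and 2-cell genes lower. Of genes used in the primitive streak, where mesoderm and endoderm arise, the growth factor Fgf8 was 49.5-fold higher (42.0 to 58.6), the mesoderm regulator T 26.6-fold (23.2 to 30.7), the posterior factor Cdx2 5.26-fold (4.98 to 5.56) and the Wnt target Sp5 6.74-fold higher (6.26 to 7.27). Hox groups 1 to 4 had a median of 1.87 (percentile 100, random range -0.60 to 0.36), with Hoxb1 16.1-fold higher (14.1 to 18.4), Wnt response genes 0.64 (percentile 100) and glycolysis genes 0.77 (percentile 99.99), with the glycolytic enzyme Eno1 3.0-fold higher (2.97 to 3.03). The primitive endoderm list had a median of -1.34 (percentile 0.0, range -0.41 to 0.28), or -0.56 averaged over cells, with Cubn 4.25-fold lower (4.17 to 4.33) and the laminin chain Lama1 4.27-fold lower (4.14 to 4.40; log2 fold -2.07, or -1.42 averaged over cells), and the 2-cell list -1.71 (percentile 0.0), with Zscan4d 6.70-fold lower (6.35 to 7.08).

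From ciToti3 to ciToti4, primitive endoderm genes stood higher and formative and naive pluripotency genes lower. The primitive endoderm list had a median of 2.34 (percentile 100, random range -0.47 to 0.49), with the receptor Pdgfra 12.8-fold (12.2 to 13.5) and Col4a2 11.1-fold higher (10.9 to 11.3). Rbp4, the retinol carrier made by yolk sac and liver (ENSMUSG00000024990, chromosome 19, 38116629 to 38125281), read 843 CPM against 64.1, a fold of 13.2 (12.9 to 13.5). The hypoxia factor Epas1 was 13.95-fold (13.3 to 14.7), the receptor Flt1 17.2-fold (16.4 to 17.9) and the transcription factor Pitx1 17.2-fold higher (16.2 to 18.2), the last with a log2 fold of 3.95, or 3.35 averaged over cells. Sarcomere genes had a median of 1.27 (percentile 100, range -0.66 to 0.49), in which the myosin light chain Myl3 was 41.6-fold (38.5 to 44.9) and the troponin Tnnc1 21.4-fold higher, and Actn2 was 7.34-fold lower. Formative genes had a median of -0.98 and naive genes -0.95 (both percentile 0.0). Pou5f1, the pluripotency factor Oct4, was 4.67-fold lower (4.6 to 4.75), the methylation cofactor Dnmt3l 5.27-fold (5.0 to 5.57) and T 3.69-fold lower (3.48 to 3.92). The 2-cell list had a median of -2.17 (percentile 0.0).

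The share of thinned cells with the 2-cell programme was 15.9% in ciToti1 (15.01 to 16.7), 3.88% in ciToti2 (3.39 to 4.42), 1.10% in ciToti3 (0.906 to 1.33) and 0.019% in ciToti4 (at most 0.104). Unthinned shares were 16.1%, 5.99%, 2.31% and 0.101%, and 11202, 1093, 804 and 571 cells were too shallow to be thinned. In their extraembryonic endoderm-like cells the thinned share was 4.90% in ciToti1, at a median depth of 1990 UMIs against 1744 in its 2C-like cells. None of the thinned cells of E3.5 and E4.5 passed, which allows shares of at most 0.206% and 0.092%, and the unthinned shares were 3.97% and 0.764%. Epiblast-like cells made up 7.195%, 43.1%, 63.1% and 18.5% of ciToti1 to ciToti4, and extraembryonic endoderm-like cells 1.58%, 32.4%, 20.6% and 65.6%. This endoderm was mostly primitive endoderm-like in ciToti2 (30.7%) and parietal endoderm-like in ciToti4 (60.2%). Primitive streak-like cells made up 7.67% of ciToti3 and 1.90% of ciToti4. Clusters left unnamed held 73.4% of ciToti1, 62.6% in cluster 7 alone, which showed 4 epiblast markers. Cluster 9, with 5 trophectoderm markers, held 10.7%, 8.13%, 4.08% and 2.42% of ciToti1 to ciToti4 and was also left unnamed.

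**Figure D2:**
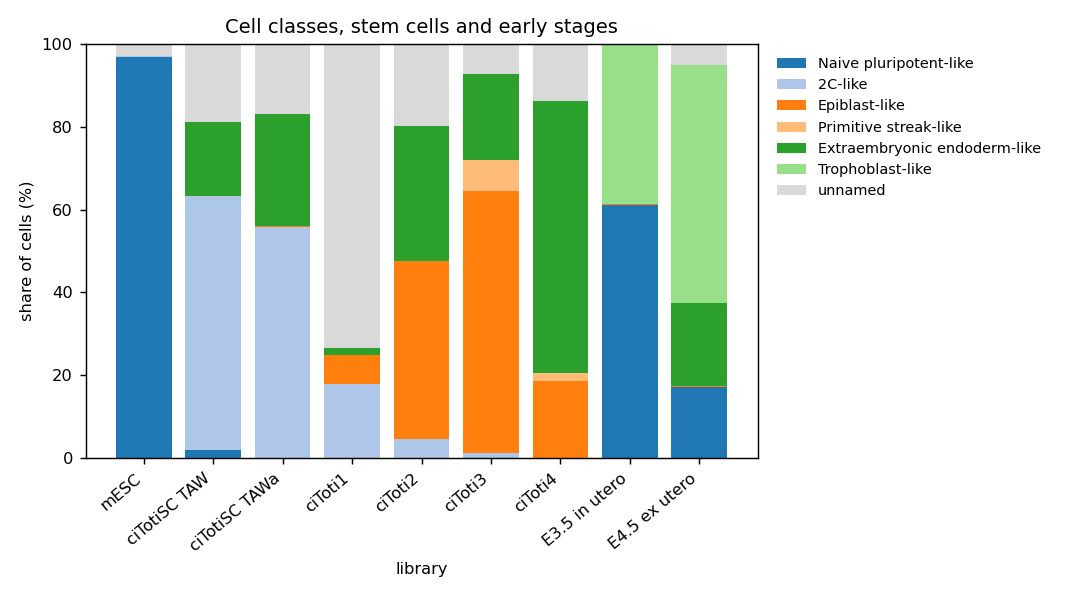
Share of cells (%) in each named class, as stacked bars per library, for the stem cells, ciToti1 to ciToti4, E3.5 and E4.5. Trophoblast-like cells appear in E3.5 (38.5%) and E4.5 (57.3%) and not in ciToti1 to ciToti4, and extraembryonic endoderm-like classes hold 65.6% of ciToti4.

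The ciToti4 library, picked like the E3.5 and E4.5 embryos, was set against both. Trophoblast genes, which build the outer layer of the blastocyst and the placenta, stood lower in ciToti4 and primitive endoderm genes higher. Against E4.5 the trophoblast list had a median of -2.03 (percentile 0.0, random range -0.23 to 0.65): Elf5, a regulator of trophoblast stem cells (ENSMUSG00000027186, chromosome 2, 103411688 to 103450989), read 0.197 against 97.9 CPM, 496-fold lower (321 to 813), Gata3 was 132-fold lower (103 to 171) and Ctsll3, a placental cathepsin, at least 6251-fold lower. Against E3.5 that list had a median of -0.80 (percentile 0.26), with Gata3 198-fold (155 to 256) and Eomes 67.5-fold lower (58.3 to 78.6). Trophoblast-like cells made up 38.5% of E3.5 and 57.3% of E4.5, and none of the 5950 cells of ciToti4 fell in that class, which allows a share of at most 0.0504% in clusters that passed the naming rule. Cluster 9, left unnamed with 5 trophectoderm markers, held 2.42% of ciToti4. Primitive endoderm genes had medians of 2.91 against E3.5 and 1.19 against E4.5 (both percentile 100), the latter 1.90 averaged over cells. Against E4.5, Col4a1 was 7.66-fold (7.54 to 7.78) and Ttr 253-fold higher (210 to 307), whereas Gata6 was 2.11-fold and Sox7 3.15-fold lower. Naive genes had medians of -2.69 and -1.66 (both percentile 0.0), and the homeobox gene Crxos was 1464-fold lower than at E3.5 (1148 to 1897). Rbp4 read 0.026 CPM at E3.5, a single UMI, and was 33053-fold higher in ciToti4 (5932 to 1305523).

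Several metabolic and imprinted lists also stood higher in ciToti4. Against E3.5, maternally expressed imprinted genes had a median of 4.43 (percentile 100), with the growth restrictor Cdkn1c 47.3-fold (38.4 to 59.0) and the long RNA H19 27.6-fold higher (25.0 to 30.5), and glycolysis genes had 2.71 (percentile 99.98), with Ldha 81.0-fold higher (75.8 to 86.8) and the hexokinase Hk2 4.93-fold lower. Against E4.5, the same 2 lists had medians of 2.38 and 1.61, hypoxia genes 1.57 and cholesterol synthesis genes 1.33.

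At E6.5 the natural embryo begins gastrulation, and ciToti7 was set against this stage in utero. Primitive endoderm genes stood higher in ciToti7 and formative pluripotency genes lower. The primitive endoderm list had a median of 2.20 (percentile 100, random range -0.36 to 0.22), with Ttr 15.3-fold (15 to 15.7) and Lama1 13.2-fold higher. The fetal serum protein Afp (ENSMUSG00000054932, chromosome 5, 90490737 to 90508907) read 531 against 10.9 CPM, 48.9-fold higher (46.2 to 51.9), and the apolipoprotein Apoa2 was 44.2-fold higher (40.02 to 49.0). Averaged over cells, the log2 folds of Ttr, Afp and Apoa2 were 2.77, 4.12 and 4.33, against 3.92, 5.49 and 5.13 for summed counts. The formative list had a median of -0.89 (percentile 0.0, range -0.38 to 0.27), with Sox3 5.01-fold (4.73 to 5.30), Utf1 3.85-fold and Pou3f1 3.81-fold lower. Wnt response genes had a median of 0.97 (percentile 99.99), with Sp5 4.72-fold and T 2.23-fold higher (2.14 to 2.31). p53 response genes had 0.99 and integrated stress response genes 1.16 (both percentile 100), with the cell cycle inhibitor Cdkn1a 9.08-fold (8.54 to 9.66) and Chac1 15.5-fold higher (13.4 to 18.1). Hypoxia genes had -0.78 and glycolysis genes -0.69 (both percentile 0.0), with the glucose transporter Slc2a1 2.35-fold lower.

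Trophoblast genes as a list did not stand apart between ciToti7 and E6.5 (median -0.14, percentile 19.39, or -0.51 averaged over cells), but Elf5 read 0.197 against 39.2 CPM, 199-fold lower (139 to 295). Trophoblast-like cells made up 0.258% of ciToti7 (0.170 to 0.375) and 11.7% of E6.5. Epiblast-like cells made up 47.2% of ciToti7 and 71.3% of E6.5, primitive streak-like cells 29.8% and 8.56%, and visceral endoderm-like cells 17.5% and 7.98%. Xist, the RNA that silences an X chromosome in female cells (ENSMUSG00000086503, chromosome X, 103460366 to 103483254), read 0.342 CPM in ciToti7 and 283 at E6.5. Flg, the skin protein filaggrin (ENSMUSG00000102439, chromosome 3, 93273523 to 93293686), read 62.8 and 0.075 CPM, a fold of 838 (425 to 1941).

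Culture outside the uterus was set against growth in utero at E6.5 and E7.5. At E6.5 the ex utero library had higher trophoblast genes (median 2.08, percentile 100, random range -0.53 to 0.32) and primitive endoderm genes (median 2.72, or 1.56 averaged over cells, percentile 100, range -0.59 to 0.32), and lower formative genes (median -1.51, percentile 0.0, range -0.57 to 0.37). Placental hormones of the prolactin family had no UMI in utero: Prl3d1 (ENSMUSG00000057170, chromosome 13, 27094190 to 27100258) read 176 CPM against 0 UMIs, at least 6258-fold higher, and Prl7a1 was at least 4030-fold higher. Plac1 was 32.0-fold (29.6 to 34.6; log2 fold 4.79, or 4.07 averaged over cells) and Lama1 22.9-fold higher (20.7 to 25.4). Otx2, an epiblast and forebrain factor, was 9.96-fold (9.41 to 10.6) and Fgf5 6.70-fold lower (6.41 to 7.02). Trophoblast-like cells made up 42.6% ex utero and 11.7% in utero, with 11.2% ex utero in ectoplacental cone or giant cell classes. Glycolysis genes had a median of -1.03 (percentile 0.0) and p53 response genes 1.24 (percentile 100), with Cdkn1a 7.88-fold higher (7.40 to 8.39).

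The E7.5 ex utero library held 681 cells, the fewest of all. Its primitive endoderm genes stood above those in utero (median 1.81, percentile 100, random range -0.53 to 0.36), with Col4a2 8.28-fold higher (7.88 to 8.69), and its visceral endoderm-like share was 50.5% (46.7 to 54.3) against 11.9%. Epiblast-like cells made up 7.64% against 25.4%, and trophoblast-like cells 15.9% against 12.8%. The p53 response list had a median of 1.07 (percentile 100), with Ccng1 4.12-fold higher (3.85 to 4.41). The amino acid transporter Slc7a3 was 19.3-fold lower (14.2 to 27.0), and Lars2 read 522 CPM against 36.1. Visceral endoderm-like cells came from cluster 7 at E7.5 in utero and from cluster 10 at E6.5 ex utero.

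**Figure D3:**
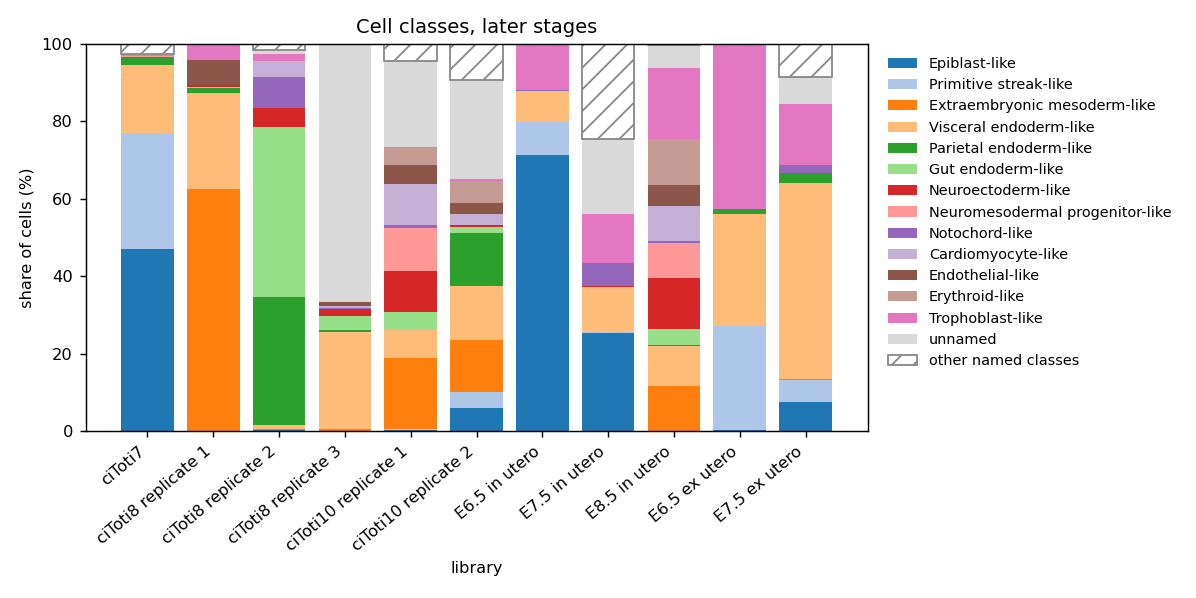
Share of cells (%) in each named class, as stacked bars per library, for ciToti7, ciToti8, ciToti10 and natural embryos of E6.5 to E8.5, with unnamed clusters in grey. Trophoblast-like cells hold 11.7% to 42.6% of the natural libraries and at most 3.93% of the model libraries, and the 3 ciToti8 libraries differ in their main classes.

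The ciToti10 libraries (n = 2) were compared with ciToti8 (n = 3) by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Counts were summed over all cells, so a change can come from the cell classes present as well as from expression within them. Erythroid-like cells numbered 513 and 299 in the ciToti10 libraries and under 50 in each ciToti8 library. Globin and erythroid genes rose: of 22244 genes tested, 16 were higher and 2 lower in ciToti10, and 8 of the higher ones belong to the fixed list of embryonic globin and erythroid genes. Hbb-y (ENSMUSG00000052187, chromosome 7, 103851749 to 103853216), an embryonic globin, read 3236 ± 3057 CPM (SD, n = 2) against 0.012 ± 0.012 (n = 3), a log2 fold of 17.53 ± 1.17 (SE, adjusted p = 0.00812). Hba-x (ENSMUSG00000055609, chromosome 11, 32276400 to 32278116), the embryonic alpha globin, read 4645 ± 1432 CPM against 0.030 ± 0.052 (log2 fold 16.96 ± 1.16, adjusted p = 0.00812). Hba-a2 (ENSMUSG00000069917, chromosome 11, 32296489 to 32297298), an adult-type alpha globin nearly identical to Hba-a1, read 141 ± 3.17 against 0.019 ± 0.003 CPM (12.46 ± 0.34, adjusted p = 8.92e-05). The ciToti8 values rest on a few UMIs, so the sizes of these folds are uncertain. The haem synthesis enzyme Alas2 (5.18), Cited4 (4.83) and Asb4 (4.58) rose on the log2 scale too. Bloc1s1, of the lysosome-related BLOC-1 complex, fell by 2.89 (SE 0.26, adjusted p = 0.0225), from 44.4 ± 3.53 to 7.48 ± 0.856 CPM. Counts of called genes were 7 without ciToti10 replicate 1, 3 without ciToti10 replicate 2, 10 without ciToti8 replicate 1, 47 without ciToti8 replicate 2 and 3 without ciToti8 replicate 3, and 74 with no filter on low counts. DESeq2 called 525 genes, 362 higher and 163 lower. With the libraries blocked by their number, edgeR called 2 genes, both higher.

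Among the fixed lists, the embryonic globin and erythroid genes rose as a group: 8 of 10 passed over all genes and 10 adjusted over the list alone (median log2 11.36, camera adjusted p = 2.91e-151, and 0.0194 with an estimated correlation). Other lists moved with the preset correlation alone. Sarcomere genes had a median of 2.27 (adjusted p = 1.15e-24, and adjusted p = 0.155 with an estimated correlation), with 0 members called by edgeR over all genes and 11 of 18 adjusted over the list alone. Of these, the cardiac actin Actc1 had a log2 fold of 6.03 (SE 0.74, adjusted p = 0.059 over all genes) and titin, Ttn, 5.41. Extracellular matrix genes had a median of 3.82 (adjusted p = 9.74e-17, and adjusted p = 0.268 with an estimated correlation), with 0 called over all genes and 9 of 12 adjusted over the list alone. In it the proteoglycan Lum had 8.57 (SE 1.09, adjusted p = 0.0638 over all genes). Its 2 ciToti10 values, 172 ± 186 CPM as a mean, were far apart. Hox groups 9 to 13 had a median of 2.18 (adjusted p = 3.15e-09, and adjusted p = 0.155 with an estimated correlation), with 0 called over all genes and 6 of 15 adjusted over the list alone. Lists that fell were hypoxia (median -0.75, camera adjusted p = 0.000426), p53 response (-0.50, 0.000558) and glycolysis genes (-0.76, 0.00151). Each had an adjusted p = 0.682 with an estimated correlation. G2 and M phase (median -0.35) and primitive endoderm genes (-0.66) also fell, and Hox groups 5 to 8 (1.81) also rose, with the preset correlation alone. Calcium handling genes passed upward in the same way, but their median was 0.04. Of these, 4 of 9 were higher when adjusted over the list alone. None of the members of these further lists was called over all genes. At an unadjusted p under 0.05, 1824 genes passed in the whole table.

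**Figure D4:**
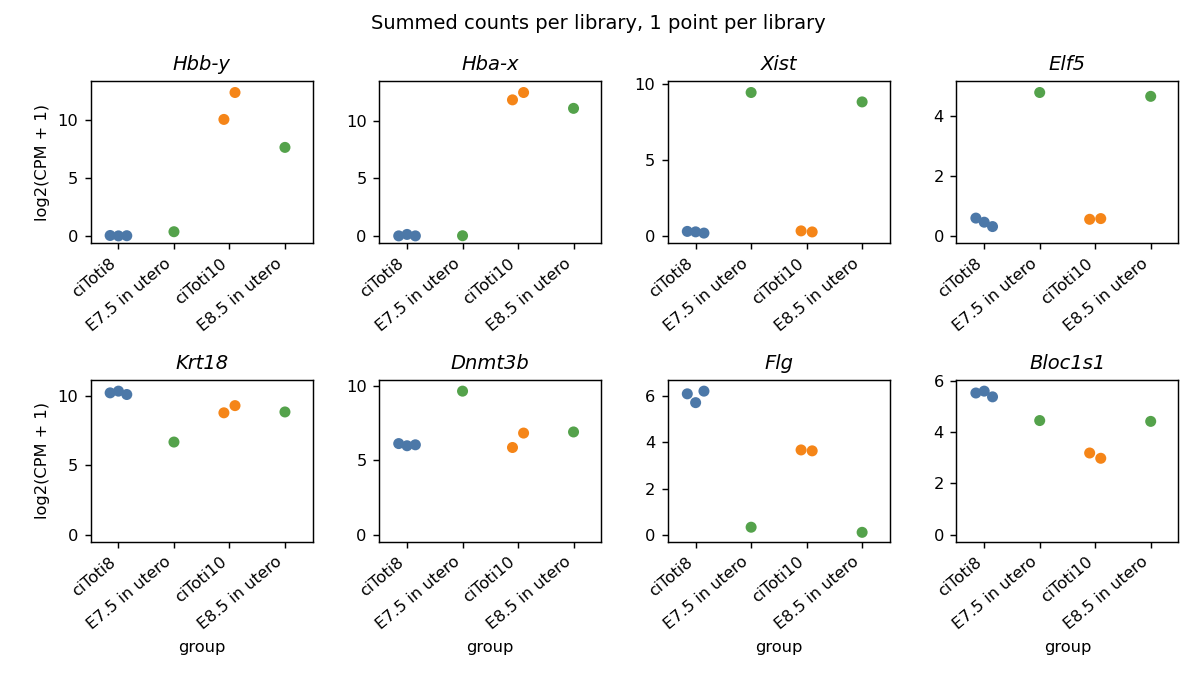
Level of 8 named genes as log2(CPM + 1), a point per library, in ciToti8 (3), E7.5 in utero (1), ciToti10 (2) and E8.5 in utero (1). Hbb-y and Hba-x are near 0 in ciToti8, Xist and Elf5 are near 0 in all 5 model libraries, and Flg is near 0 in both natural libraries.

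The ciToti8 libraries (n = 3) were compared with E7.5 in utero (n = 1) in the same model. Epiblast-like cells numbered 2479 of 9759 at E7.5 and under 50 in at least 1 ciToti8 library, so this class was not tested alone. The folds over all cells can thus come from the cell classes present as well as from expression within them. Dnmt3b (ENSMUSG00000027478, chromosome 2, 153649450 to 153687730), the DNA methyltransferase of the early epiblast, fell by 3.5 on the log2 scale (SE 0.37, edgeR quasi-likelihood adjusted p = 0.0441), reading 64.8 ± 3.33 CPM against 796. Elf5 fell by 6.04 (SE 0.46, adjusted p = 0.015), reading 0.374 ± 0.135 CPM against 26.6. Krt18 (ENSMUSG00000023043, chromosome 15, 102028180 to 102032027), a keratin of simple epithelia, rose by 3.68 (SE 0.40, adjusted p = 0.0487), reading 1199 ± 101 CPM against 101. Pde4d (ENSMUSG00000021699, chromosome 13, 108449948 to 109953461), a phosphodiesterase, rose by 4.86 and Flg by 8.17. The neural plate factor Zic5 fell by 4.19, the splicing factor Cwc22 by 3.65, Ldb2 by 4.69, Bmerb1 by 4.52 and Asb4 by 4.21. For Cwc22 the E7.5 in utero library stood apart, at 429 CPM against 31.9 to 97.0 CPM in the other natural libraries. The ciToti8 libraries read 31.6 ± 2.25 CPM. Xist is used in female cells, and whether its level followed the sex of the cells was not tested. Xist fell by 11.71 (adjusted p = 0.000248), reading 0.188 ± 0.047 CPM against 687, and Tpm3-rs7 (ENSMUSG00000058126, chromosome 14, 113314608 to 113316754), a tropomyosin retrogene whose reads can come from its parent, fell by 3.14. In all, 7 genes were higher and 16 lower by edgeR, and 3570 passed at an unadjusted p under 0.05. The count was 1 without ciToti10 replicate 1, 2 without ciToti10 replicate 2, 9 without ciToti8 replicate 1, 48 without ciToti8 replicate 2 and 2 without ciToti8 replicate 3, and it was 13 with doublets left out, 42 with no filter on low counts and 2 with only these groups in the fit. DESeq2 called 777 genes higher and 691 lower.

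The lists that moved in ciToti8 against E7.5 lost their calls with an estimated correlation. Formative genes had a median of -1.44 (camera adjusted p = 8.95e-09, and adjusted p = 0.368 with an estimated correlation), where Dnmt3b was the 1 member called over all genes and 7 of 12 were lower when adjusted over the list alone. The epiblast factor Pou3f1 in it had a log2 fold of -2.13 (adjusted p = 0.166 over all genes). Cholesterol synthesis genes had a median of 1.43 (adjusted p = 8.58e-09, and adjusted p = 0.538 with an estimated correlation), with 0 called over all genes by edgeR and 11 of 16 adjusted over the list alone. Its members Cyp51 and Fdft1 had log2 folds of 2.44 (adjusted p = 0.139) and 2.03 (adjusted p = 0.135). The dissociation response list, immediate early genes switched on during tissue digestion, had a median of 2.20 (adjusted p = 5.49e-06, and adjusted p = 0.538 with an estimated correlation), with 0 called over all genes and 5 of 12 adjusted over the list alone. Among these Atf3, which the integrated stress response list also holds, had a log2 fold of 5.14 and Jun 2.82. DNA methylation genes had a median of -1.06 (adjusted p = 4.59e-05, and adjusted p = 0.531 with an estimated correlation), with 5 of 10 lower when adjusted over the list alone. The p53 response list had a median of 1.02 (adjusted p = 0.000936, and adjusted p = 0.538 with an estimated correlation), with 4 of 12 adjusted over the list alone, and Cdkn1a had a log2 fold of 3.34 (adjusted p = 0.152 over all genes). The trophoblast list did not pass (median 0.17, test direction down, adjusted p = 0.292). Its members went both ways, with Krt18 higher and Elf5 lower.

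Within visceral endoderm-like cells the same comparison called 739 genes higher and 835 lower in ciToti8 of 15536 tested (edgeR quasi-likelihood test). The cells came from clusters 4, 5 and 29 in the models and cluster 7 at E7.5. Cdkn1a rose by 6.04 on the log2 scale (SE 0.55, adjusted p = 0.00193), from 6.4 to 364 CPM, the epithelial keratin Krt19 by 7.04 (SE 1.60, adjusted p = 0.0305), the mucosal peptide Tff3 by 6.21 (SE 1.20, adjusted p = 0.0216), Ms4a10 by 7.74 (SE 0.94, adjusted p = 0.00647) and the immediate early gene Fosb by 5.90 (SE 1.32, adjusted p = 0.0291). Aass, an enzyme of lysine breakdown, fell by 4.39 (SE 0.45, adjusted p = 0.00359), and the transporter Slc16a9 by 5.63 (SE 0.61, adjusted p = 0.00433). Of the fixed lists, 9 of 12 dissociation response genes, 5 of 12 p53 response genes, 4 of 16 cholesterol synthesis genes and 4 of 12 integrated stress response genes rose, and 3 of 10 DNA methylation genes fell. Leaving out ciToti8 replicate 2 gave 383 called genes, leaving out ciToti8 replicate 3 gave 226 and leaving out ciToti8 replicate 1 gave 1167, while leaving out ciToti10 replicate 1 or 2, which share the fit, gave 2464 and 2516, and 26% of cluster 29 carried a high doublet score.

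The ciToti10 libraries (n = 2) were compared with E8.5 in utero (n = 1) in the same model, and 7 genes of 22244 were called. Hba-a2 rose by 5.17 on the log2 scale (SE 0.39, edgeR quasi-likelihood adjusted p = 0.0168), reading 141 ± 3.17 CPM against 3.35, and Flg rose by 7.17 (SE 0.61, adjusted p = 0.0326). Elf5 fell by 5.88 (SE 0.54, adjusted p = 0.046), reading 0.479 ± 0.018 CPM against 24.2, and Xist by 11.17 (SE 0.44, adjusted p = 0.00104). Tpm3-rs7 and the gene models Gm10260 and Gm10320, which resemble copies of other genes, fell by 5.35, 8.18 and 5.8, and at an unadjusted p under 0.05, 1351 genes passed. Without ciToti10 replicate 1 or replicate 2 edgeR called 0 genes (1083 and 1498 at an unadjusted p under 0.05), without ciToti8 replicate 2 it called 17 and without ciToti8 replicate 3 it called 2, and it called 20 with only these groups in the fit and 12 with no filter on low counts. DESeq2 called 83 genes higher and 121 lower.

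Among the lists, trophoblast genes had the smallest camera p against E8.5 with the preset correlation (median -1.98, camera adjusted p = 1.80e-15, and adjusted p = 0.257 with an estimated correlation). In it Elf5 was the 1 member called over all genes, and 6 of 15 were lower when adjusted over the list alone. Ascl2, a factor of the ectoplacental cone, had a log2 fold of -4.84 (adjusted p = 0.13 over all genes) and Tfap2c -3.36 (adjusted p = 0.292). Extracellular matrix genes had a median of 3.81 (adjusted p = 1.86e-08, and adjusted p = 0.572 with an estimated correlation), with 0 called by edgeR over all genes and 4 of 12 adjusted over the list alone. Globin and erythroid genes had a median of 0.92 (adjusted p = 5.23e-06, and adjusted p = 0.257 with an estimated correlation), with Hba-a2 called over all genes and 4 of 10 adjusted over the list alone.

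Within erythroid-like cells of ciToti10 and E8.5, edgeR called 11 genes higher and 15 lower in a fit of 3 libraries with 1 residual degree of freedom, so that the spread came from the ciToti10 pair. Hba-a2 rose by 6.71 (SE 0.67, adjusted p = 0.000212), the cytokine receptor Csf2rb by 5.37 (SE 0.64, adjusted p = 0.00105) and the anion exchanger Slc4a1 by 3.75 (SE 0.65, adjusted p = 0.031), while the homeobox protein Hopx fell by 4.69 (SE 0.46, adjusted p = 0.000212). With RLE scaling no gene passed (481 at an unadjusted p under 0.05), and at Leiden resolution 2 the count was 12. In extraembryonic mesoderm-like cells, in a fit that also had 1 residual degree of freedom, 2 genes were higher and 14 lower. These cells came mostly from cluster 18 in ciToti10 (2067 and 612 cells) and from clusters 18 (619) and 35 (523) at E8.5. The metallothioneins Mt1 and Mt2 fell by 3.12 (SE 0.48, adjusted p = 0.039) and 4.07 (SE 0.52, adjusted p = 0.00874). The count was 32 with RLE scaling and 5 at Leiden resolution 2. Pde4d rose in endothelial-like cells (4.09, SE 0.49, adjusted p = 0.0331), extraembryonic mesoderm-like cells (4.85, adjusted p = 0.00714) and visceral endoderm-like cells (6.27, adjusted p = 0.0059). Endothelial-like cells gave 7 called genes (1 residual degree of freedom), or 39 with RLE scaling and 45 at Leiden resolution 2. Visceral endoderm-like cells, from cluster 27 at E8.5, gave 12, or 21 without ciToti10 replicate 1. In gut endoderm-like cells edgeR called 0 of 13301 genes (425 at an unadjusted p under 0.05), or 14 and 17 without ciToti8 replicate 2 and 3, and in cardiomyocyte-like cells, with 1 residual degree of freedom, it called 2, among them Xist, and 0 without ciToti8 replicate 2 (157 at an unadjusted p under 0.05).

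Within visceral endoderm-like cells of ciToti10 against ciToti8, 4 genes were higher and 4 lower by edgeR. The vesicle GTPase Rab25 rose by 5.08 (SE 0.50, adjusted p = 0.0137) and the serine protease hepsin, Hpn, by 3.43 (SE 0.35, adjusted p = 0.0137), and the histone gene Hist1h2ap fell by 4.45 (SE 0.47, adjusted p = 0.015). Hbb-y also passed, at 51.7 CPM in ciToti10 against 3236 CPM in its whole libraries, a level that free RNA from red cells can reach. The count was 17 without ciToti10 replicate 1, 19 without ciToti10 replicate 2, 5 without ciToti8 replicate 2 and 3 without ciToti8 replicate 3.

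Cell classes differed between the numbered libraries of a group by more than counting error. In ciToti8, extraembryonic mesoderm-like cells made up 62.4% of replicate 1, with a mean of 21.0% ± 35.8 (SD, n = 3). Replicate 2 held 43.8% gut endoderm-like and 33.0% parietal endoderm-like cells, and replicate 3 held 25.0% visceral endoderm-like and 66.6% unnamed cells, 60.5% in cluster 28 alone. Visceral endoderm-like cells averaged 17.1% ± 13.7 in ciToti8 (n = 3) and 10.6% ± 4.78 in ciToti10 (n = 2), against 11.9% at E7.5 and 10.52% at E8.5. Trophoblast-like cells averaged 1.86% ± 1.97 in ciToti8 and 0.314% ± 0.371 in ciToti10, against 12.8% at E7.5 and 18.4% at E8.5. In the models these cells came mainly from cluster 13, where Elf5 read 8.33 to 27.4 CPM per library. Trophoblast-like cells of the natural libraries of E6.5 to E8.5 read 97.9 to 299 CPM.

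In ciToti10, replicates 1 and 2 held 10.7% and 2.63% cardiomyocyte-like cells (E8.5 9.09%), 10.48% and 0.56% neuroectoderm-like cells (E8.5 13.3%), 11.01% and 0.04% neuromesodermal progenitor-like cells (E8.5 8.97%), 4.44% and 5.57% erythroid-like cells (E8.5 11.7%), and 18.1% and 13.4% extraembryonic mesoderm-like cells (E8.5 11.5%). Parietal endoderm-like cells made up 13.5% of replicate 2 and 0.10% of replicate 1. Unnamed clusters held 22.3% and 25.6% of the 2 libraries and 6.01% of E8.5, with 21.7% of replicate 1 in cluster 20 and 22.8% of replicate 2 in cluster 15.

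In dissected heart tissue, ciToti12 was set against E10.5. Extracellular matrix and posterior Hox genes stood higher in ciToti12, and calcium handling and globin genes lower. The matrix list had a median of 2.47 (percentile 100, random range -0.15 to 0.46), with Lum (ENSMUSG00000036446, chromosome 10, 97565128 to 97572703) at 518 against 13.9 CPM, 37.1-fold higher (35.5 to 38.9), Postn, a protein of valves and fibroblasts, 25.8-fold (24.9 to 26.7) and the collagen Col1a1 9.57-fold higher (9.43 to 9.72). Hox groups 9 to 13 had a median of 3.53 and groups 5 to 8 a median of 2.70 (both percentile 100), with Hoxa10 139-fold higher (104 to 190). Nppa (ENSMUSG00000041616, chromosome 4, 148000722 to 148002079), the atrial natriuretic peptide, read 1.70 against 107 CPM, 63.0-fold lower (54.4 to 73.5), and the ventricular light chain Myl2 was 24.7-fold lower (23.3 to 26.1). Calcium handling genes had a median of -0.72 (percentile 0.0, range -0.24 to 0.48), with phospholamban, Pln, 5.50-fold lower (5.12 to 5.90), and sarcomere genes -0.15 (percentile 1.54), with Myl7 1.33-fold, Tnnt2 1.21-fold and Myh6 1.54-fold higher. Cardiac transcription factors had a median of 0.54 (percentile 99.25), with Hand1 15.5-fold higher (14.9 to 16.2) and the ventricular factor Irx4 7.18-fold lower, and the pacemaker channel Hcn4 was 3.40-fold higher (3.10 to 3.73). Globin and erythroid genes had a median of -3.82 (percentile 0.0), or -4.47 averaged over cells, with Hbb-y 25.99-fold lower (25.9 to 26.1), and the platelet factor Pf4 read 0.343 against 222 CPM. Averaged over cells, Hbb-y had a log2 fold of -5.71 and Pf4 of -6.77, against -4.70 and -7.38 for summed counts.

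Cardiomyocyte-like cells made up 10.4% of ciToti12 (9.65 to 11.1) and 8.88% of E10.5 (8.43 to 9.34). Cluster 19 of this class came nearly all from E10.5, and cluster 7 came mostly from ciToti12. Extraembryonic mesoderm-like cells held 32.0% of ciToti12 and hepatocyte-like cells 9.01%, against 0 (at most 0.0196%) and 2.41% at E10.5. Erythroid-like cells held 15.95% of E10.5 and 0.53% of ciToti12, second heart field-like cells 15.6% and 0.09%, and endocardial-like cells 1.99% and 0.02%. These shares leave out unnamed clusters, among them cluster 8, with Nfatc1 and Hapln1 among its top genes (2.95% of E10.5 and 3.19% of ciToti12), and clusters 5 (1.69% and 7.2%) and 9 (9.09% and 0.649%), whose best list was that of the second heart field with 2 and 3 markers. Clusters 10 and 26 both passed the epicardial marker rule and were not compared as 1 type. Cluster 10, led by Shox2, Tbx18 and the pacemaker channel gene Hcn4, held 7.17% of ciToti12 and 0.595% of E10.5, and cluster 26, led by the epicardial genes Upk3b and Aldh1a2, held 4.09% of E10.5 and no cell of ciToti12 (at most 0.0453%). Unnamed clusters held 29.2% of ciToti12, 15.4% in cluster 1, and 39.0% of E10.5, 10.6% in cluster 24.

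**Figure D5:**
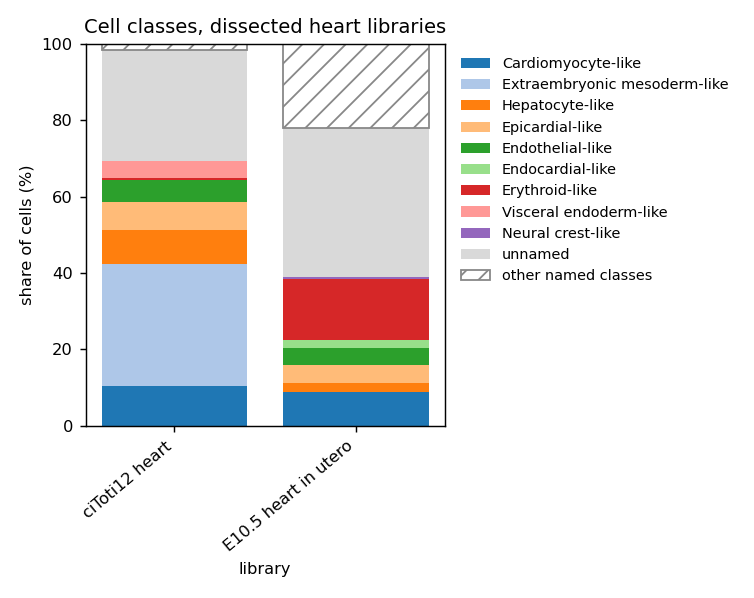
Share of cells (%) in each named class, as stacked bars, for the ciToti12 and E10.5 heart libraries, with unnamed clusters in grey. Cardiomyocyte-like cells hold 10.4% and 8.88%, and extraembryonic mesoderm-like cells hold 32.0% of ciToti12. The epicardial-like class is cluster 10 in ciToti12 and mostly cluster 26 at E10.5.

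Each library was last compared with every natural library across genes. The stem cell libraries lay closest to E4.5 ex utero (Spearman correlation 0.630 for mESC, 0.627 for TAW and 0.647 for TAWa). No natural library was earlier than E3.5, so a match to an earlier stage was not possible. ciToti1, ciToti2 and ciToti3 lay closest to E6.5 in utero (0.696, 0.754 and 0.776), ciToti4 to E6.5 ex utero (0.784) and ciToti7 to E6.5 in utero (0.884). Of the ciToti8 libraries, replicates 1 and 3 lay closest to E8.5 (0.843 and 0.841) and replicate 2 to E7.5 in utero (0.768), and other gene sets or Pearson correlation changed the closest library for each of them. Both ciToti10 libraries lay closest to E8.5 (0.863 and 0.830), and ciToti12 to the E10.5 heart (0.846). The E10.5 heart was the only natural heart library, and no whole embryo was later than E8.5. These last matches therefore cannot place a stage. Among themselves the ciToti8 libraries correlated at 0.797 to 0.919 and the ciToti10 libraries at 0.878.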

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

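The tests of the difference between the 2 stages, and for the trophoblast pattern the tests of the place of Elf5 UMIs and of left-out barcodes put back, the limit on the level in unnamed clusters, the values of ciToti10 replicate 1 alone and the interval and left-out library of the pooled test, were chosen only after the results had been seen. The gap between ciToti10 and E8.5 was set against the gap between ciToti8 and E7.5, as the difference of those log2 folds. No single gene of 22244 passed edgeR's quasi-likelihood test of that difference (0 called, 1683 at an unadjusted p under 0.05), and 11 gene lists passed camera's test with the preset correlation. None of these 11 passed with an estimated correlation.

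Globin and erythroid genes had a median difference of 2.58 (camera adjusted p = 1e-06, and adjusted p = 0.499 with an estimated correlation), so they stood higher relative to the natural embryo in ciToti10 than in ciToti8. Formative pluripotency genes differed by 1.39 (adjusted p = 7.47e-05, and adjusted p = 0.499 with an estimated correlation) and extracellular matrix genes by 1.43 (adjusted p = 0.0051, and adjusted p = 0.641 with an estimated correlation). DNA methylation genes differed by 0.44 (adjusted p = 0.00911, and adjusted p = 0.641 with an estimated correlation) and calcium handling genes by 0.37 (adjusted p = 0.0309, and adjusted p = 0.586 with an estimated correlation). Dissociation response genes differed by -2.11 (adjusted p = 3.56e-05), p53 response genes by -0.70 (adjusted p = 0.00422), cholesterol synthesis genes by -1.0 (adjusted p = 0.00436), hypoxia genes by -1.03 (adjusted p = 0.00436) and glycolysis genes by -0.91 (adjusted p = 0.00553). With an estimated correlation each of these last 5 lists had an adjusted p = 0.641. Trophoblast genes differed by -1.75 (adjusted p = 6.94e-05, and adjusted p = 0.525 with an estimated correlation).

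Trophoblast-like cells and the trophoblast regulator Elf5 were scarce in ciToti7, ciToti8 and ciToti10. For the share of cells, a place of such cells in unnamed clusters stays open: the highest of those clusters with at least 100 model cells read Elf5 at 0.675 CPM against 36.2 CPM in the lowest trophoblast-like cluster, but with so few Elf5 UMIs none could have passed 21.7 CPM, and unnamed clusters held 10.7% of the models' Elf5 UMIs (95% interval 7.14 to 15.3), not clearly below their 14.9% of all UMIs. Loss of trophoblast cells at the filter on barcodes was argued against for the level of Elf5. It was also argued against for the share of cells outside ciToti10 replicate 1. Over all barcodes of a library, whatever their cluster and with every left-out one put back, Elf5 was at most 0.513 CPM in these models. It was at least 24.1 CPM in the natural libraries of E6.5 to E8.5. Outside ciToti10 replicate 1, the share would reach at most 6.07% were every left-out barcode such a cell. In those natural libraries it was at least 10.4%. In ciToti10 replicate 1, where the limit of 6.07% was instead 16.5%, left-out barcodes read Elf5 at 0.606 CPM (1 UMI, at most 3.38 CPM). Those of the models, pooled, read 1.92 CPM (5 UMIs, 95% interval 0.623 to 4.48, or 4.195 without ciToti10 replicate 1). Left-out barcodes of those natural libraries read 3.99 to 94.9 CPM, above the 3.38 CPM of ciToti10 replicate 1. The lowest of these values rest on 2 UMIs at E8.5 (3.99 CPM) and 1 UMI at E7.5 in utero (4.38 CPM). Loss therefore stays open in ciToti10 replicate 1. The level to be met is thus not known. A hypothesis that stays open is that the models hold few cells of this lineage, and loss during dissociation was not tested.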

How the results depend on the processing

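Among these tests, the minimum of 5000 UMIs per cell and the leaving out of single libraries within cell classes were chosen only after the results had been seen. None of the recomputed folds of named genes reversed its direction. Nor did any recomputed list median between single libraries whose main value lay outside the range of random lists. A reversal was not looked for in the other values. Of the 1680 recomputed medians of gene lists between single libraries, 1669 stayed within their bounds and 11 moved. Of 1200 recomputed folds of named genes between single libraries, 963 stayed and 237 moved, and of 2079 recomputed class shares 1471 stayed and 608 moved. Of 348 recomputed tests of 28 named genes, 238 gave the same call and 110 lost it. These losses were 2 with RLE scaling, 5 with doublets left out, 11 with only the 2 groups in the fit, 21 and 24 without ciToti10 replicate 1 and 2, 13 and 24 without ciToti8 replicate 1 and 3, and 10 with a replicate block. Of 90 list tests, 36 lost the call with an estimated correlation and 54 gave the same result, nearly all of which had no call to lose. The only call kept was that of globin and erythroid genes in ciToti10 against ciToti8 (camera adjusted p = 0.0194).

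Counts of genes called over all cells moved by over 1.5 times in these cases. For ciToti10 against ciToti8, ciToti8 against E7.5 and ciToti10 against E8.5, no filter on low counts gave 74, 42 and 12, and DESeq2 gave 525, 1468 and 204. Leaving out doublets gave 13 for ciToti8 against E7.5. With only the 2 groups in the fit, that comparison gave 2 and ciToti10 against E8.5 gave 20, where fewer libraries set the spread. Leaving out each numbered library in turn gave 3 to 47 genes for ciToti10 against ciToti8 (lowest without ciToti10 replicate 2 or ciToti8 replicate 3, highest without ciToti8 replicate 2), 1 to 48 for ciToti8 against E7.5 (without ciToti10 replicate 1 and ciToti8 replicate 2), and 0 to 17 for ciToti10 against E8.5 (without either ciToti10 library and without ciToti8 replicate 2). The 0 came from edgeR with 1083 and 1498 genes at an unadjusted p under 0.05. Where ciToti10 was left with 1 library, that library was assumed to vary like the others. The causes of the other moves were not tested.

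A replicate block gave 2 genes for ciToti10 against ciToti8. Deviations of same-numbered libraries from their group mean correlated at -0.138 and 0.068. With 2 ciToti10 libraries the deviations within that group mirror each other. These values therefore cannot tell whether same-numbered libraries share more than a number.

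Within classes, RLE scaling gave 39 genes in endothelial-like, 32 in extraembryonic mesoderm-like and 0 in erythroid-like cells (edgeR, 481 at an unadjusted p under 0.05) for ciToti10 against E8.5. Leiden resolution 2 gave 45 in endothelial-like, 12 in erythroid-like, 5 in extraembryonic mesoderm-like and 0 in cardiomyocyte-like cells (edgeR, 232 at an unadjusted p under 0.05), and 5 in extraembryonic endoderm-like cells of ciToti8 against E7.5. Leaving out each ciToti8 and ciToti10 library of a fit in turn gave 3 to 19 genes in visceral endoderm-like cells of ciToti10 against ciToti8, 226 to 2516 in those of ciToti8 against E7.5 and 10 to 21 in those of ciToti10 against E8.5. In all extraembryonic endoderm-like cells together it gave 0 to 1, 0 to 27 and 0 to 8 by edgeR for the same comparisons, where all libraries gave 1, 11 and 5 (364 to 2905 at an unadjusted p under 0.05 beside the counts of 0). For ciToti10 against E8.5, it gave 0 to 17 in gut endoderm-like cells (0 without either ciToti10 library, with 553 and 497 at an unadjusted p under 0.05), 6 in endothelial-like, 15 in extraembryonic mesoderm-like and 0 in cardiomyocyte-like cells (157 at an unadjusted p under 0.05), where the last 3 fits each held 1 ciToti8 library to leave out. Leaving out a ciToti10 library could not be done in these 3 classes or in erythroid-like cells, since no residual degrees of freedom were left.

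Averaging over cells in place of summing gave list medians of 5.92 for the 2-cell programme in TAWa against mESC, and for primitive endoderm genes 2.99 in ciToti2 against ciToti1, -0.56 in ciToti3 against ciToti2 and 1.78 in ciToti7 against E6.5. The 2C-like share of TAW was 59.3% with at least 1000 genes per cell, 59.5% with doublets left out, 56.2% with at least 5000 UMIs per cell, 59.3% at Leiden resolution 2 and 59.8% with each library clustered alone. The extraembryonic endoderm-like share of ciToti4 was 68.5%, 64.4% and 69.1% under the first 3 of these settings, 76.8% at Leiden resolution 0.5 and 64.3% at resolution 2. The cardiomyocyte-like share of ciToti12 was 14.3% at resolution 2 and 11.2% clustered alone, and the trophoblast-like share of ciToti7 was 0.0% clustered alone. With 500 variable genes the closest library was E7.5 ex utero for ciToti8 replicate 1 (0.818) and E7.5 in utero for replicate 3 (0.831), and for replicate 2 it was E8.5 over all genes of at least 10 CPM (0.898) and by Pearson correlation (0.774). The share of cells with the 2-cell programme in TAW was 68.6% at 1 UMI, 45.0% at 10 UMIs and 70.0% without thinning, and in TAWa 65.9%, 34.8% and 68.2%. Counts were simulated for ciToti10 against ciToti8 with the spread of these libraries (21556 genes). Of the genes changed 4-fold, 72% were called (72 of 100), and of those changed 16-fold, 100% (100 of 100), with 19 false calls. In this run the false calls made up more than the 0.05 that the adjustment aims at. The changed genes were drawn from those with a mean of at least 20 CPM, so these shares do not cover genes with lower counts. Depth limits ciToti1 and E3.5 most, with medians of 1680 and 2450 UMIs per cell.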

Other observations

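The tests of the Cell Ranger version and of the genotype of the stem cell libraries, the interval of the Y-linked ratio and the check for shared clusters were chosen only after the results had been seen, and the other tests before. Imprinted genes, used from a single parental copy, were among the lists that stood apart between the heart libraries. Maternally expressed members had a median log2 fold of 2.04 in ciToti12 against E10.5 and paternally expressed members 1.33 (both percentile 100 of random lists). H19 read 1788 against 311 CPM and the growth regulator Dlk1 1245 against 274 CPM, while Grb10 read 206 against 710 CPM. The p53 response list had a median of 1.0 (percentile 100), with the death receptor Fas 38.5-fold higher (33.4 to 44.7), and S phase genes -0.51 (percentile 0.0). In the stem cells, oocyte and maternal genes had a median of -1.20 in TAW against mESC (percentile 0.03), with Ooep, of the subcortical maternal complex, at 139 against 809 CPM.

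Several genes set whole kinds of libraries apart. Flg read 0.045 to 0.254 CPM in the 8 natural libraries, 11.4 to 74.2 CPM in the 11 libraries of ciToti1 to ciToti12 and 16.01 to 24.2 CPM in the 3 stem cell libraries. Pde4d read 34.0 to 516 CPM, 757 to 1777 CPM and 1476 to 1504 CPM in the same order. Xist was at most 4.88 CPM in the ciToti libraries, and it was also low in the natural libraries of E7.5 ex utero (0.254 CPM) and E10.5 (0.275 CPM). In these natural libraries Y-linked genes summed to 203 and 211 CPM, against 36.7 to 127 CPM in the other natural libraries. Whether Xist followed the sex of the cells was not tested. The gene model Gm10260 read 457 to 588 CPM in the stem cell libraries and 402 to 1141 CPM in natural libraries, but 1.37 to 10.4 CPM in ciToti1 to ciToti12. Y-linked genes summed to 5.24 to 16.3 CPM in the stem cell libraries against 33.8 to 209 CPM in the ciToti libraries. On the log2 scale, genes of chromosome 8 had medians of 0.337 to 0.403 in the stem cells and -0.086 to 0.202 in the ciToti libraries. In natural libraries these were -0.109 to 0.042. Those of chromosome 14 had 0.346 to 0.551, -0.108 to 0.059 and -0.091 to 0.052 in the same order.

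Gm10260, Y-linked genes and chromosomes 8 and 14 thus set the stem cell libraries apart from ciToti1 to ciToti12. The Cell Ranger version was argued against for Gm10260, since natural libraries counted with the version of most ciToti libraries read at least 401.81 CPM. A difference in cell types cannot be told apart from other causes for chromosomes 8 and 14: within extraembryonic endoderm-like cells their genes stood 0.449 above those of other autosomes (95% interval 0.374 to 0.516), but TAW and TAWa cells lay in cluster 5, those of ciToti2 to ciToti4 in clusters 12, 14 and 15, and mESC had none. A hypothesis that stays open beside it is extra copies of chromosomes 8 and 14 in the stem cell libraries. In those cells these had the 2 highest medians of 19 autosomes (rank sum 3, the lowest possible). Both chromosomes had already stood out in the whole TAW and TAWa libraries that hold these cells, so the rank is not independent support. Over whole libraries, chromosomes 8 and 14 had medians of 0.337 and 0.346 in mESC and 0.403 and 0.507 in TAW. Naive pluripotent-like cells made up 12025 of 12416 cells in mESC but 168 of 8471 in TAW, where 5192 were 2C-like. These values argue against either class alone as the source of the rise, and leave other differences in cell types open. Whether the ciToti libraries came from other cells than the stem cell libraries was not tested.

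In ciToti8 replicate 1, 0.418% of extraembryonic mesoderm-like, 0.855% of endothelial-like and 0.442% of extraembryonic ectoderm-like cells had a Y-linked UMI after thinning to 5000 UMIs, against 22.4% of parietal and 34.9% of visceral endoderm-like cells (unthinned 0.949% of the mesoderm-like and 69.5% of the visceral endoderm-like cells, median depths 12264 and 19619 UMIs). Fewer UMIs per cell were argued against, since the thinned share of the mesoderm-like cells was 0.012 of that of the visceral endoderm-like cells. Low use of these genes in extraembryonic mesoderm was argued against, since the lower such ratio in the ciToti10 libraries was 0.685 (95% interval 0.594 to 0.791), above the 0.5 that this explanation allows, though the interval spans the bound of 0.67 set for the test. Cells of the genotype of the stem cell libraries were argued against by Gm10260, at 12.01 CPM in the mesoderm-like, 11.3 in the endothelial-like and 9.32 in the extraembryonic ectoderm-like cells. Cells that lack Y-linked transcripts for another reason may make up these 3 classes in this library, which was not tested.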
